A study of Mus musculus with 6 samples.

How the data were processed

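RNA was measured in primary mouse pre-B cells, the B-lymphocyte precursors that grow from fetal liver on irradiated ST2 stromal cells with the cytokine IL-7. Per the labels' protocols, the cells were transduced with a retroviral vector that encodes HA-tagged wild-type Ikaros and, through an internal ribosome entry site, GFP, or with a control vector that encodes GFP alone. RNA was taken 48 h after infection from 3 biological replicates of each group, amplified, labelled with biotin and hybridised to 1-colour Affymetrix mouse gene arrays, on which a transcript cluster is a set of probes along a gene. The labels do not say whether the replicates came from separate litters or whether cells were sorted for GFP.

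The deposited table holds 35556 rows and 6 arrays, with no missing values. The deposited values were taken as log2 signals: they run from 3.39 to 14.46 with 2 decimals, which fits log2 of a scanner's range, but no label states the scale. Background correction, summarisation, normalization and software are not given in the sources used here. The array medians lie between 6.49 and 6.59, and the arrays' quantiles are not identical. The values were used as deposited. Correlations between arrays ran from 0.990 to 0.998. No detection calls were used, so whether a dim cluster lies above background is unknown, and the number of arrays limits the precision.

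Clusters were named through the platform annotation. A single gene symbol was given for 21789 rows, several for 1621 and none here for 12146. The rows with at least 1 symbol, 23410 in all, were tested. Of the rows with 1 symbol, 21698 matched the reference gene table by gene ID and 0 symbols differed. Genes with several rows (999) were represented in lists and named by the row with the highest mean over all 6 arrays, which left 19938 genes.

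Ikaros was compared with the control vector by limma 3.58.1 (lmFit and eBayes with default settings, R 4.3.3) on all 6 arrays, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A permutation of 3 against 3 arrays cannot go below p = 0.1 (exact, two-sided), so no single-gene permutation test was used. Fold values are 2 to the power of the difference in mean log2 value, each mean is given with its SD, and SE is that of the limma coefficient.

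The labels number the replicates 1 to 3 in both groups without saying that a number marks a shared culture. After removal of the group means, arrays with the same number correlated across clusters at 0.68, 0.19 and 0.56 for replicates 1, 2 and 3. All 3 values exceeded 0.1, the bound set beforehand, so the numbers were taken to pair the samples. The deviations of a group's 3 arrays cancel, so the values are not independent and do not establish that a number marks a shared culture. For 5 of the 6 arrays the best partner in the other group had its own number; Ikaros replicate 2 correlated better with control replicate 3 (0.38). The fit without the block was set as the principal one before the data were examined, and the fit with the replicate number as a block, called the paired fit, is given beside it where it changes a call.

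The 27 gene lists, which hold 594 genes of which 540 were measured, were fixed from general knowledge before the data were examined, and 34 genes are in more than 1 list. Lists were tested with camera (two-sided) at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists; camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. Members were counted over all clusters tested and adjusted over the list alone.

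Genes were named by a rule fixed beforehand: Ikzf1; up to 12 genes with the largest rise and 12 with the largest fall among called clusters with 1 symbol whose groups do not overlap; and up to 4 members of a list with the smallest p, plus members that go against their list. Predicted genes, unnamed clones, small RNAs and olfactory receptors were counted but not named. The same rule was applied to the paired fit, with the same direction in all 3 pairs in place of no overlap; that extension, the paired fit's own alternatives and a set of immunoglobulin clusters were chosen after the values were seen.

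Both fits were tested on simulated data for this comparison, in 5 runs over 23410 clusters with 200 changed clusters each. Without the block, 11.8% of clusters changed by 0.5, 91.3% of those changed by 1 and 97.6% of those changed by 1.5 on the log2 scale were recovered, and 0.444% of calls were false. With the block, 64.8%, 99.4% and 99.4% were recovered, and 5.58% of calls were false. The simulation drew variances within pairs from limma's own fitted prior, added independent normal errors, and gave arrays of the same number a shared effect. The shares of false calls hold under these assumptions and do not measure those of the real fits. The alternatives tried were quantile normalization, median centring, all rows of the table, 2 filters on dim clusters (the median and the 25th percentile of mean signal), eBayes with trend and robust, array weights, the replicate block, each array left out in turn, 1 row per gene, stricter thresholds and the other set tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No coordinates are given, since no genome build is named in the sources used here.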

Results

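The series asks how gene expression in cultured mouse pre-B cells changes when the amount of Ikaros is raised. Ikaros, encoded by Ikzf1, is a zinc finger DNA-binding protein of lymphocytes. RNA from 3 cultures that received the Ikaros vector and 3 that received the GFP control vector was measured 48 h after infection on 6 arrays, and 23410 transcript clusters with a gene symbol were tested. The deposited values, taken as log2 signals, had medians of 6.50, 6.59 and 6.55 on the Ikaros arrays and 6.49, 6.55 and 6.51 on the control arrays.

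The Ikzf1 cluster was higher in every Ikaros culture. It read 12.61 ± 0.07 (SD, n = 3) with Ikaros and 11.58 ± 0.07 with the control vector, a difference of 1.03 on the log2 scale (SE 0.07) or 2.04-fold, with limma adjusted p = 0.00989. The differences in the 3 pairs were 1.04, 1.01 and 1.03. Whether the cluster's probes lie in the part of the gene that the vector carries was not examined. How far the cluster reads the vector's transcript beside that of the cells is therefore unknown. The adjusted p was above the threshold when rows without a gene symbol were also tested (0.0702) and without Ikaros replicate 2 (0.0767), Ikaros replicate 3 (0.0613) or control replicate 2 (0.0840), while the difference stayed between 0.99 and 1.06 in each fit that left out 1 array.

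Among the called genes Cd2, a lymphocyte adhesion receptor, rose 4.41-fold, from 7.93 ± 0.15 to 10.07 ± 0.33 (adjusted p = 0.00989). S1pr1, the sphingosine-1-phosphate receptor that guides lymphocytes out of tissues, rose 3.51-fold, from 7.28 ± 0.15 to 9.09 ± 0.08 (adjusted p = 0.00317). Jchain, which joins IgM and IgA into polymers, rose 3.13-fold, from 6.41 ± 0.14 to 8.05 ± 0.31 (adjusted p = 0.0244). Fcrl1, an Fc receptor-like protein of B cells, rose 2.51-fold, from 6.48 ± 0.10 to 7.81 ± 0.05 (adjusted p = 0.00348). Second in size, Neurl3, a ubiquitin ligase, rose 3.95-fold, the prostaglandin D synthase gene Hpgds 2.72-fold, and the calcium channel gene Cacna1i 2.18-fold. Cpm, a carboxypeptidase, rose by 0.91 (SE 0.09) on the log2 scale, and Pim2, a survival kinase, by 0.72 (SE 0.08). A cluster shared by Igkc and several Igkv4 symbols rose by 1.48 (SE 0.15). The single cluster that fell was Vat1l, from 9.97 ± 0.15 to 8.88 ± 0.12, with a log2 difference of -1.09 (SE 0.10, adjusted p = 0.0244).

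These 12 clusters, 11 higher and 1 lower, were all that passed in the principal fit. An unadjusted limma p below 0.05 was found for 1655 clusters, or 7.07%, where a share of 0.05 is expected without any difference. In the paired fit 566 were called higher and 105 lower, or 84.4% higher, and the 12 were among them. After quantile normalization the paired fit gave 73.7% higher. At an unadjusted p below 0.05 the paired fit had 2000 higher and 1535 lower, against 1991 and 2188 after quantile normalization and 1474 and 1890 without replicate 2. Without Ikaros replicate 1 the principal fit called 154 higher and 4 lower. That fit kept control replicate 1, and replicate 1 stood apart in both groups, as set out below. Its counts therefore mix the difference with Ikaros and that between replicates. The principal fit called 3 higher and 0 lower without Ikaros replicate 2 or control replicate 2. It called 4 higher and 0 lower without Ikaros replicate 3 or control replicate 3. S1pr1 and Fcrl1 were called in each of these fits. With rows that carry no symbol included, the principal fit kept S1pr1 and Fcrl1 and the paired fit called 1 cluster, shared by Iglv1, Iglc1 and Iglv2. With any pair left out the paired fit called 0, with 1575 to 3364 clusters at an unadjusted limma p below the threshold. Its variance then rests on few arrays (limma's prior degrees of freedom 2.02 to 2.65 against 5.71), so 0 calls says little on any single pair.

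Further genes passed in the paired fit and not without the block. Ms4a1, which encodes CD20, rose from 7.34 ± 0.24 to 9.01 ± 0.41, a 3.17-fold difference (paired adjusted p = 0.00140; 0.0662 without the block). Bank1, a scaffold of B-cell receptor signalling, rose by 1.67 on the log2 scale, and its control arrays were spread widely (7.36 ± 1.12). Cd55, which restrains complement, rose by 1.49, Ly6d, a surface marker of B-lineage commitment, by 1.48, and the kappa variable gene Igkv6-20 by 1.51. Dnase1l3, a secreted DNase, had the largest rise of the named genes at 2.33, from 6.53 ± 0.29 to 8.86 ± 0.59, and Eqtn, known from the sperm acrosome, rose by 1.45.

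Among the named genes that fell in the paired fit, the interferon-induced gene Ifitm3 had a log2 difference of -1.23 (paired adjusted p = 0.00210), the cystatin gene Cst7 one of -0.88, and Vipr2, a neuropeptide receptor, one of -0.87. Kit, the stem cell factor receptor of early progenitors, fell from 7.92 ± 0.83 to 7.34 ± 0.52 (paired adjusted p = 0.0492), and after quantile normalization its paired adjusted p was 0.0560. Igf2, a fetal growth factor, had pair differences of -0.94, -0.57 and -0.59 over a spread of 1.40 (SD) among the controls. Frmd4b, Megf10, Ica1, Inka1, Htra3 and the metallothionein gene Mt2 had log2 differences of -0.77, -0.71, -0.61, -0.59, -0.57 and -0.57. None of the genes in this group passed without the block.

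**Figure D1:**
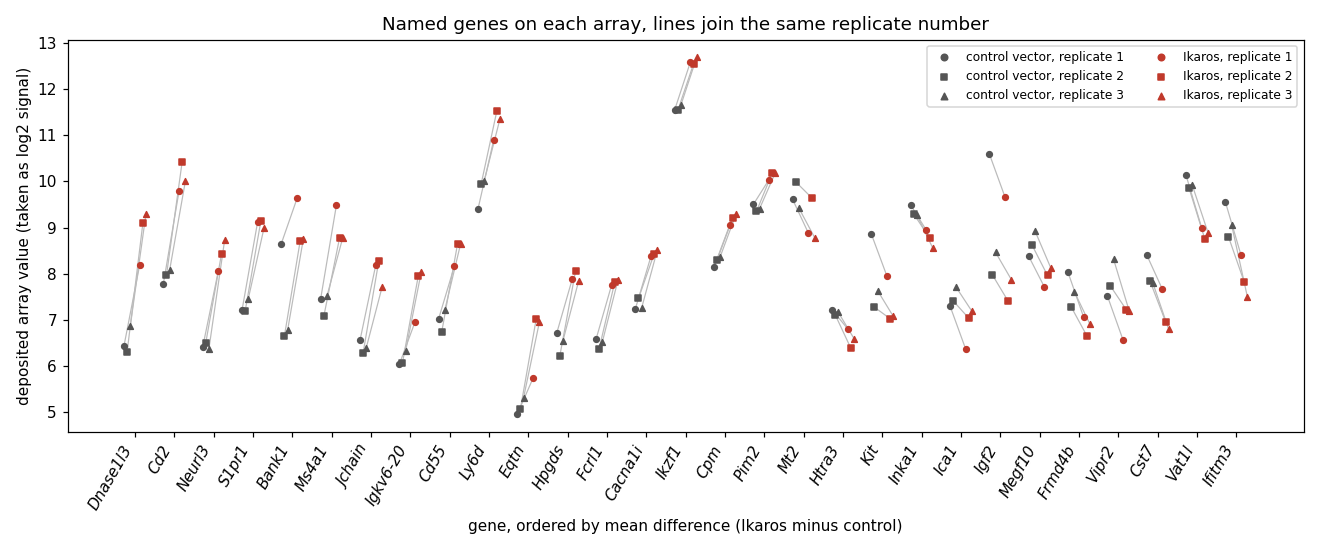
Deposited array value, taken as log2 signal, of each named gene on the 6 arrays, with grey points for control vector, red points for Ikaros, marker shapes for the replicate number and lines that join the same number. The Ikzf1 lines run in parallel, with pair differences of 1.04, 1.01 and 1.03, while the Kit and Igf2 values of replicate 1 lie above those of the other replicates in both groups.

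Markers of late B-cell stages shifted upward as a list. Here and below, a shift is a camera call at the preset correlation. Other groupings of the arrays also gave such calls, as set out after the lists. The median difference of 27 measured genes was 0.35, and 23 were above 0 (camera adjusted p = 1.41e-13). Cd2 rose in the principal fit, 11 members rose when adjusted over the list alone, and 14 rose in the paired fit, among them Cd55, Ms4a1 and Cxcr5, the homing receptor for B-cell follicles, with a difference of 0.80. With an estimated correlation this was the only list called without the block (adjusted p = 0.0261); in the paired fit its adjusted p was 0.157 with an estimated correlation.

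Genes of pre-B cell receptor signalling also shifted upward, with a median of 0.24 over 20 genes and 17 above 0 (camera adjusted p = 1.32e-09; adjusted p = 0.149 with an estimated correlation, and 0.304 in the paired fit). None rose over all clusters without the block, 11 rose when adjusted over the list alone, and 7 rose in the paired fit. The kinase gene Syk rose from 11.01 ± 0.08 to 11.50 ± 0.07 and the adaptor gene Blnk from 11.78 ± 0.08 to 12.27 ± 0.15 in the paired fit. Rasgrp3, which activates Ras, rose by 0.70, and the kinase gene Blk by 0.75. The surrogate light chain genes went the other way without a call: the differences were -0.06 for Igll1, -0.12 for Vpreb1 and -0.13 for Vpreb2.

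B-lineage transcription factors had a median of 0.15 over 26 genes, with 21 above 0 (camera adjusted p = 1.53e-06; adjusted p = 0.412 with an estimated correlation). In the paired fit 6 rose, and 7 rose when adjusted over the list alone without the block. Foxo1 rose by 0.58, Bcl6 by 0.51, Sox4 by 0.48 and Spi1, which encodes PU.1, by 0.37. Antigen receptor recombination genes had a median of 0.14 over 18 genes (camera adjusted p = 0.000151; adjusted p = 0.414 with an estimated correlation), and 12 were above 0. In the paired fit 6 rose, and 4 rose when adjusted over the list alone without the block. The recombinase genes Rag1 and Rag2 rose from 9.74 ± 0.46 to 10.91 ± 0.29 and from 8.49 ± 0.35 to 9.14 ± 0.22, and Spib rose by 0.44. The 4 that rose over the list alone were Rag1, Rag2, Spib and Foxo1. Spib and Foxo1 are transcription factors that the list before this one counts as well. Of the recombination list, 6 members were below 0, with Xrcc5 at -0.20 without a call.

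Targets of FOXO factors and genes of quiescence had the highest median of the lists, 0.51 over 21 genes with 20 above 0 (camera adjusted p = 2.15e-13; adjusted p = 0.256 with an estimated correlation). S1pr1 rose in the principal fit, 7 members rose when adjusted over the list alone, and 12 rose in the paired fit, with Sesn1 at 0.39, Bcl6 at 0.51 and Rag1 at 1.17. Genes that restrain glucose uptake and energy supply had a median of 0.15 over 16 genes (camera adjusted p = 0.000126; adjusted p = 0.412 with an estimated correlation). In the paired fit 5 rose, among them the cannabinoid receptor gene Cnr2 at 0.82, Pik3ip1, an inhibitor of PI3 kinase, at 0.74, and Sesn3 at 0.47; 3 rose when adjusted over the list alone without the block. Cell cycle inhibitors had a median of 0.10 over 17 genes (camera adjusted p = 0.00437; adjusted p = 0.414 with an estimated correlation). The antiproliferative genes Btg2 and Btg1 rose by 0.81 and 0.71 in the paired fit, in which 3 members rose; 0 passed without the block, and without control replicate 1 the list's camera adjusted p was 0.0788.

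Genes of DNA replication and of ribosome biogenesis shifted downward. The S-phase list had a median of -0.22 over 29 genes, with 28 below 0 (camera adjusted p = 4.66e-15; adjusted p = 0.256 with an estimated correlation). Tyms, the thymidylate synthase gene, fell in the paired fit, from 10.80 ± 0.06 to 10.42 ± 0.05. Pola1, Chaf1a and Gins1 had differences of -0.29, -0.25 and -0.28 without a call; 2 members fell in the paired fit, 1 when adjusted over the list alone without the block, and 20 so adjusted in the paired fit. The MYC and ribosome biogenesis list had a median of -0.27 with all 29 members below 0 (camera adjusted p = 5.67e-11; adjusted p = 0.453 with an estimated correlation). In the paired fit 6 fell, with Dkc1 at -0.35 and Gnl3 at -0.38, and Nop56 and Nop58 had differences of -0.30 and -0.29 without a call. No member passed over the list alone without the block, and 24 fell so adjusted in the paired fit. Genes of G2 and mitosis were not called (median -0.02 over 29 genes, camera adjusted p = 0.463), but without Ikaros replicate 2 they were, downward, with a median of -0.08 (camera adjusted p = 0.0120); Cdc25b rose by 0.52 in the paired fit, and none was called over the list alone without the block.

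Interferon response genes had a median of 0.08 over 26 genes, with 17 above 0 and 9 below. The camera adjusted p was 0.000964, and 0.149 with an estimated correlation. The medians in pairs 1, 2 and 3 were 0.175, 0.025 and 0.055, so the shift was largest in pair 1. In the paired fit 4 rose, namely Zbp1, Ddx58, Ifit3 and Gbp3 at 0.45, 0.86, 0.53 and 0.56. When adjusted over the list alone without the block, 3 rose. The interferon-induced Ifitm3, which is not in the list, fell, at -1.23. Adhesion, homing and migration genes had a median of 0.08 over 26 genes (camera adjusted p = 0.00161; adjusted p = 0.149 with an estimated correlation). In the paired fit 5 rose, S1pr1, S1pr4 and Rhoh among them, and Ctnnd1, which encodes a catenin, fell, with a difference of -0.45; adjusted over the list alone without the block, 3 rose and 1 fell. Cholesterol and lipid synthesis had a median of -0.08 over 20 genes (camera adjusted p = 0.0473; adjusted p = 0.699 with an estimated correlation). None of its members passed in either fit or over the list alone, with Fasn at -0.24, and the list's call was lost after quantile normalization (adjusted p = 0.0843), above the median or the 25th percentile of mean signal (0.0743 and 0.0650) and without Ikaros replicate 3 (0.912), control replicate 1 (0.209) or control replicate 2 (0.0515). Without Ikaros replicate 3 its median was 0.025, above 0. The list's medians in pairs 1, 2 and 3 were -0.02, -0.04 and -0.21, so the shift lay mainly in pair 3.

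In all, 12 lists shifted without the block, 9 upward and 3 downward, and 15 in the paired fit, 11 upward and 4 downward. Every other split of the arrays into equal groups also gave shifted lists without the block, from 1 to 13. The other splits with no whole pair on one side gave 5 to 7. A list's adjusted p at the preset correlation therefore does not by itself set Ikaros against control apart from other groupings. The paired fit added apoptosis regulators and p53 targets (paired camera adjusted p = 0.0164, with 4 members risen and Bmf, a cell death gene, at 1.09), immediate-early genes (0.0106, with 2 risen and Jund at 0.40) and, downward, glycolysis and glucose uptake (0.0106). In the glycolysis list Hk2 fell, at -0.36, while the transporter gene Slc2a6 rose, at 0.95. The glycolysis medians in pairs 1, 2 and 3 were -0.04, -0.07 and -0.31, so that shift lay mainly in pair 3. The immediate-early medians were 0.08, 0.235 and 0.03, the largest in pair 2. Over the list alone without the block, 1 apoptosis regulator rose, and no immediate-early or glycolysis gene was called. With an estimated correlation 1 list was called without the block and 0 in the paired fit. The lowest adjusted p in the paired fit was then 0.157, and those of the apoptosis, immediate-early and glycolysis lists were 0.304, 0.304 and 0.505. A higher correlation does not account for every lost call. In the paired fit the late B-cell and MYC lists, both at 0.157, had estimated correlations of -0.018 and -0.0088, under the preset 0.01. Without the block the interferon and adhesion lists had 0.0046 and -0.0047, so the setting changes more than the correlation. At that setting camera also rests on the residual degrees of freedom of the arrays, which are few and fewest with the block. Its power is then low, so the 0 calls in the paired fit do not argue against a shift of any list. Fry called 4 lists without the block and 5 with it. Without it these were late B-cell markers (fry adjusted p = 9.998e-05), apoptosis regulators (0.0404), pre-B cell receptor signalling (0.0463) and adhesion (0.0463). With it they were late B-cell markers, apoptosis regulators, pre-B cell receptor signalling, FOXO targets and MYC. The MYC list had a fry adjusted p of 0.367 without the block. The S-phase list was called by fry in neither fit (0.0838 without the block, 0.0781 with it).

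**Figure D2:**
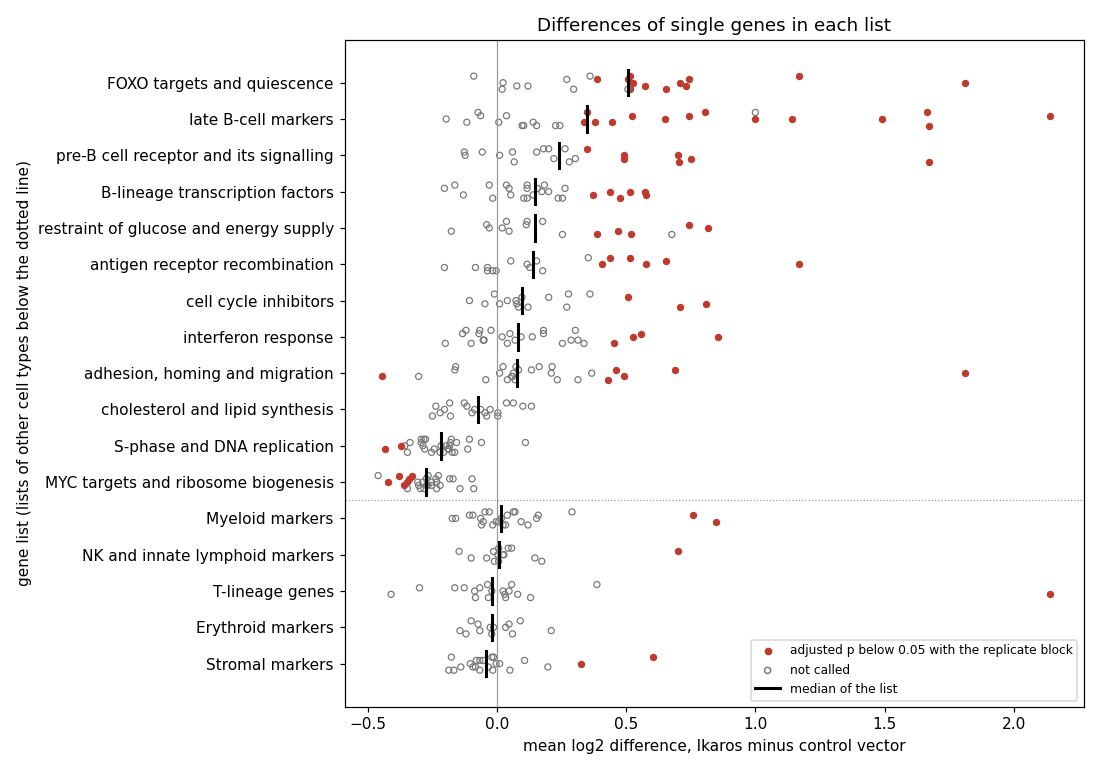
Mean log2 difference, Ikaros minus control vector, of each measured gene in the 12 shifted lists and, below the dotted line, in the 5 lists of other cell types; filled points passed in the paired fit and black bars are list medians. The medians run from -0.27 for the MYC and ribosome biogenesis list to 0.51 for the FOXO list, while those of the other cell types lie between -0.04 and 0.02.

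Markers of other cells that the cultures could hold did not shift as lists. Medians were -0.04 for stromal genes (22 measured, camera adjusted p = 0.555), 0.02 for myeloid genes (25, 0.241), -0.02 for erythroid genes (13, 0.555), 0.01 for NK and innate lymphoid genes (15, 0.515) and -0.02 for T-lineage genes (19, 0.555); the NK median was below 0 after median centring. Single members rose in the paired fit, namely Csf1 at 0.60 and 1 other of the stromal list, Csf2rb at 0.76 and Cybb at 0.85 of the myeloid list, Klrd1 at 0.70 of the NK list, and Cd2, which B-lineage cells also express. Adjusted over the list alone without the block, 1 stromal, 3 myeloid and 1 T-lineage gene rose and no erythroid or NK gene did. Without Ikaros replicate 1 or control replicate 3 the stromal list's camera adjusted p was 0.0269 or 0.0437, both downward, and without Ikaros replicate 2 the myeloid list's was 0.0385, upward, with a median of 0.045.

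The IL-7 receptor and STAT5 list did not shift (median -0.08 over 19 genes, camera adjusted p = 0.485), and Pim2 was its only called member in either fit and, without the block, over the list alone. The Notch list had a median of -0.03 over 17 genes (0.329), with 4 members risen in the paired fit, among them Dtx1 at 0.41, Heyl at 0.46 and Maml1 at 0.35; after quantile normalization the paired adjusted p of Dtx1 was 0.0660, and 1 member rose over the list alone. Progenitor genes had a median of 0.06 over 20 genes (0.485), and in the paired fit Sox4 and Satb1 rose, by 0.48 and 0.60, and Kit fell; 1 rose over the list alone. Of the Ikaros family with its NuRD and Polycomb partners (median -0.03 over 26 genes, 0.555) Ikzf1 was the only member called in either fit and over the list alone. The unfolded protein response (median -0.03 over 20 genes, 0.780) and canonical histone genes (median -0.01 over 8 genes, 0.780) had no called member, and the histone median was above 0 after quantile normalization. Median and mean differed in sign for the IL-7, Notch, T-lineage, Ikaros family and unfolded protein response lists, of which camera followed the mean in the first 3 and the median in the others.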

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

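The paired fit's alternatives and gene naming, and the separation of variance model and adjustment, were chosen after the data were seen. Of the 11 higher and 1 lower clusters, all rows of the table left 2 and 0, where rows without a symbol spread more (median residual SD 0.143 against 0.0834 in the paired fit), and Ikzf1 then had a difference of 1.03 with adjusted p = 0.0702. With the variance model over all rows but p adjusted over rows with a symbol, 3 and 0 were called; with separate variance models and p adjusted over all rows, 8 and 1. The count of higher clusters was 57 with trend and robust, 72 with array weights (Ikaros replicate 1 had the lowest weight, 0.568), 566 with the replicate block (105 lower), 21 with 1 row per gene and 5 (0 lower) at an adjusted p below 0.01. Over the fits that left out 1 array the count ran from 3 to 154, with 0 to 4 lower. At an unadjusted limma p below 0.05 these fits had 1028 to 3380 clusters, the lowest under the share of 0.05 expected without any difference. Across them the Ikzf1 difference ran from 0.99 to 1.06 and the number of shifted lists from 11 to 16. The 154 came without Ikaros replicate 1 but with control replicate 1, which had a weight of 1.19 in the weighted fit. Replicate 1 stood apart in both groups, so its difference from the others enters the 154 and the 72. The 12 shifted lists became 1 with an estimated correlation and 4 by fry.

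With the replicate block, the 566 higher and 105 lower clusters became 1 and 0 with all rows of the table. They became 0 and 0 without any replicate number, where few arrays remain, with 1575 to 3364 at an unadjusted limma p below 0.05. With the variance model over all rows alone they were 1 and 0, and with the adjustment over all rows alone 423 and 52, so most of the loss came with the shared variance model. The lower clusters numbered 202 after quantile normalization, 180 above the median signal and 292 with trend and robust. The 15 shifted lists became 0 with an estimated correlation, where camera has little power, and 5 by fry. For the other alternatives, unless fewer arrays show it, the cause was not tested.

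Under the other settings the counts stayed within 1.5 times. Ikzf1, whose lost calls are given in the Results, is left out of the gene counts that follow. Over comparisons of a result with a setting, the 10 other named genes called without the block kept the call in 100 of 140 and lost it in 40. Uncalled genes gained one in 96 of 1541. The 12 called lists kept it in 165 of 192 and lost it in 26, uncalled lists gained one in 18 of 237, and 1 called list turned its median, cholesterol and lipid synthesis without Ikaros replicate 3 (0.025, camera adjusted p = 0.912, against -0.08; range without 1 array -0.1325 to 0.025). With the block, calls were kept in 272 of 554 and lost in 282 for genes, and kept in 117 of 150 and lost in 33 for lists, with 14 of 395 and 2 of 117 gained. No called gene turned its direction. Median centring and the fit without control replicate 1 each kept 9 of the 12 called clusters and lost Cpm (adjusted p = 0.0652 and 0.0877), Pim2 (0.0826 and 0.0877) and the cluster shared by Igkc and several Igkv4 symbols. The fits without Ikaros replicate 2 or 3 or control replicate 2 or 3 kept 3, 4, 3 and 3. No detection calls were at hand, so signal over background limits the dim clusters to an unknown extent.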

Other observations

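The immunoglobulin clusters, chosen after their values were seen, and the tests of other lineages and culture stages were set after the results were known, as were the rule on which controls inform and the trend test restricted to them; the other tests were set before. All 19 clusters with a kappa light chain symbol were above 0, with a median of 1.23 and quartiles of 0.83 and 1.48; 1 rose without the block and 16 in the paired fit. Both clusters shared by lambda symbols (Iglv1, Iglc1 and Iglv2) rose in the paired fit, by 2.78 and 2.90, one from 9.26 ± 0.64 to 12.04 ± 0.69. The 4 clusters with a heavy chain variable symbol had a median of 0.36, and 1 rose; the 6 with a heavy chain constant symbol alone had a median of 0.37, and none was called.

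The rise of light chain clusters was set against technical explanations. If signal of any immunoglobulin transcript accounted for it, the heavy chain variable clusters would have a median of at least 0.615, and of at most 0.3075 if not; their 0.36 lay between these bounds, so this stays open, as does the sharing of probes among light chain genes, for which no probe sequences were used. The test of cells of another lineage, with a smallest adjusted p of 0.241 for an upward shift among 5 marker lists, says nothing on this rise, because those cells do not supply light chain transcripts. A difference in the cells brought by Ikaros stays open as well and was not tested.

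Of the clusters called in the paired fit 84.4% were higher with Ikaros. The tables argue against dim clusters as the whole account: above the median mean signal 77.1% were higher, past the bound of 75% set for that outcome. After quantile normalization the higher calls went from 566 to 565 and the lower ones from 105 to 202, so the share fell to 73.7% through the greater number of lower calls. Array scaling stays open for the balance alone: that share lies between the bounds of 60% and 75%, and at an unadjusted p below 0.05 the paired fit then had 1991 higher and 2188 lower.

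The difference with Ikaros resembled differences between control cultures in some pairs. Control 3 minus control 1 gave list medians of 0.51 for FOXO targets and -0.44 for MYC and ribosome biogenesis, but 0.03 for late B-cell markers. If the cultures stood at different stages of the same change, each pair's difference would correlate across clusters with the difference of the other 2 controls; Pearson's r was -0.0814, 0.382 and 0.220 (Spearman's rho -0.15, 0.37 and 0.25) for pairs 1, 2 and 3. The controls were ordered by the first principal component of all 6 arrays, Ikaros arrays included, so the signs of r are partly built in. The explanation by stages stays open. The lowest r comes from control 3 minus control 2, whose FOXO list median was 0.11 against 0.40 in pair 1. By that list these controls differ little. On the component they lay at 3.81 and -6.40, and Ikaros 1 and control 1 at -14.7 and -25.7, so by it they do differ. Both other values go with the explanation, within the limit on their sign. After the trend with signal was removed r was -0.0305, 0.361 and 0.211. For pairs 2 and 3, where the controls differ by the FOXO list, the lowest stayed at 0.211 against a bound of 0.1. In these 2 pairs that argues against a trend with intensity as the whole account. The test as first set, over all 3 pairs, was undecided, since pair 1 was under the bound before the correction. Clusters are not independent replicates.

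The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 11 clusters higher, 1 lower and 12 in all, and 1 split, the real one, gave as many in each case, with 0 as the highest of the others. Among the 4 splits that part all 3 pairs, the real one gave 671 in the paired fit and the others 0. For lists, 4 of the 10 splits gave at least the 12 of the real one, with 13 as the highest other; the 3 others that reached 12 or 13 keep a whole pair on each side. Among the 4 splits that part all pairs, too few for a share under 0.05, the real one gave 12 lists and the others 5, 5 and 7.

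Replicate 1 stood apart in both groups. Xist read 11.96 and 11.95 on the arrays of replicate 1 and 12.83 to 13.04 on the others, and the Y-linked Uty read 7.18 and 7.01 against 5.70 to 5.97. Igf2 read 9.66 and 10.60 against 7.40 to 8.46. Both control differences that informed on culture stages, 3 minus 1 and 2 minus 1, use control 1, so what sets replicate 1 apart enters them. The 12146 rows without a symbol here, tested with limma together with the others, gave 0 calls in both fits. At an unadjusted limma p below 0.05 there were 411 higher and 157 lower without the block. Together these are less than a share of 0.05 of the rows, which is expected without any difference. With the block there were 985 and 340.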
